A study of Drosophila melanogaster with 4 samples.

How the data were processed

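The series holds 4 Affymetrix Drosophila Genome 2.0 arrays, hybridised with RNA from pools of Canton-S flies labelled as 30 males and 30 females each. The groups were young flies (1 to 3 days, with both titles giving day 1 and the design text 3 days) and old flies (40 days), each with 0 or 100 µM curcumin in the food, with 1 array per group. Groups were taken from the labels. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column, converted to biotin-labelled cRNA and hybridised by the manufacturer's procedure. The submitters' processing notes name MAS5, the array maker's summary of the probes of a probe set, and its version is not given in the sources used here.

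The deposited values were taken as log2 MAS5 signals per probe set, because they ranged from -4.67 to 13.4 and gave, after back-transformation, trimmed mean signals of 149, 139, 151 and 151 for the young arrays without and with curcumin and the old arrays without and with it. The back-transformed signals were rescaled to a common 2% trimmed mean, as MAS5 does, with factors of 0.991, 1.06, 0.975 and 0.976. They were then floored at the 40th percentile pooled over the arrays, a signal of 19.3, and log2-transformed. Between 58.6% and 60.8% of probe sets were at or above the floor per array. No detection calls were used. A fold against a side below the floor is a lower bound, computed against the floor and written as at least N-fold, and values at the floor were not ranked.

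Probe sets were named from the platform table and updated by gene number to the gene table of assembly Release 6. Of 18769 probe sets, 13646 had 1 gene, 402 had several and 4721 had no gene name in the table. Of those with 1 gene, 13543 matched the current gene table and the others kept the platform's symbol. Only probe sets with 1 gene were used, and for the 1094 genes with more than 1 the probe set with the highest mean log2 signal stood for the gene. The design text counts 18880 probe sets. Any probe sets named as controls were dropped on loading, and the planned check of noise on spike-in controls was not run. Pairs of probe sets of the same gene were used alone.

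For each of the 4 pairs of arrays, the log2 difference and the number of genes at least 2-fold apart were computed over genes at or above the floor on at least 1 array of the pair, with no p-value. The age effect over both diets and the curcumin effect over both ages were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on an additive model of age and curcumin, over 9563 genes at or above the floor on at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05. This model has 1 residual degree of freedom per gene, which holds noise and any interaction together, and the prior had 3.08 degrees of freedom and an SD of 0.20. Nothing in the labels says whether the pools came from separate cultures, so these p-values measure only the spread between the arrays. The interaction could not be tested. Correlations are across genes, 9 relations in all. Values for comparison came from simulated arrays without effects, drawn with the noise of the limma prior and not floored.

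For 33 gene lists the median difference and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, were computed as a description of these arrays. Named genes were the 10 most positive and 10 most negative for age among genes at or above the floor on all arrays and at least 2-fold the same way in both diets, and the same for curcumin. The 6 largest each way were added for curcumin at each age, the 5 largest each way for the interaction, up to 4 bounds each way per comparison, up to 4 members per list, and the genes mth, Thor, InR and bsk. Some further list members are given as examples of a count and were picked after their values were seen. Groups, tests, lists, alternatives and this rule were set before the data were examined.

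The limma script was tested on simulated data for the age effect with 9563 genes, noise drawn with the fitted prior and 200 changed genes. It called 0% of 67 genes changed 2-fold, 49.3% of 67 changed 4-fold and 71.2% of 66 changed 8-fold, gave the right direction for 100% of each, and called 3 unchanged genes. Alternatives were quantile normalization, no rescaling, centring on each array's median, no floor, floors at the 25th and 60th percentiles, the mean over a gene's probe sets, a pseudocount in place of the floor, a 3-fold threshold, an intensity trend with a robust prior, a model without the other factor, and leaving out each array. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.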

Results

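RNA from whole-fly pools of the Canton-S strain of Drosophila melanogaster was measured on 4 Affymetrix Drosophila Genome 2.0 arrays, 1 for each combination of age and diet. The young flies were 1 to 3 days old and the old flies 40 days old per the labels, and each pool was labelled as 30 males and 30 females. Each age was kept either on food with 100 µM curcumin, a plant polyphenol from turmeric, or on food without it. As adults, young flies could have been on that food for at most 3 days and old flies for up to 40. Age and time on curcumin food therefore cannot be told apart where curcumin differences are compared between the ages. The study asked which genes differ with age, and whether curcumin feeding alters expression in young and in old flies. The values used hold 18769 probe sets, of which 13646 named exactly 1 gene and gave values for 11981 genes. Between 76.3% and 79.2% of these genes were at or above the floor of 19.3 signal units on each array. With 1 array per group, no difference between a pair of arrays has a replicate check, so values are given as higher or lower and carry no p-value. The number of arrays limits the precision of every value.

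Old flies without curcumin had higher signals for 8 of 12 antimicrobial peptide genes and lower signals for most digestive proteases than young flies without curcumin. These 8 peptide genes were at least 2-fold higher and the other 4 at least 2-fold lower, with a median log2 difference of 1.99 that stood at percentile 100 of 10000 random lists matched on expression. The diptericin gene DptB read 4087 in old and 261 in young flies, 15.7-fold higher. The infection-induced gene edin was below the floor in young flies and read 2131 in old flies, at least 110-fold higher. The metchnikowin gene Mtk was 3.97-fold higher, the defensin gene Def 3.95-fold higher and the attacin gene AttD 6.02-fold higher. The 4 members at least 2-fold lower were Drsl3, Drsl4, Drsl5 and Anp, the last encoding andropin of the male ejaculatory duct, which read 1244 in old and 6522 in young flies. Among 30 immune recognition and signalling genes, 8 were at least 2-fold higher and 0 lower, with a median of 0.63 at percentile 100. They included the recognition protein PGRP-SB1 (log2 difference 2.06), the NF-kappaB factor gene Rel (1.44) and the NF-kappaB inhibitor gene cact (1.08).

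Digestive proteases had the lowest list median of this comparison among lists with 3 or more measured genes, at -1.98 (percentile 0), and 19 of 24 were at least 2-fold lower. Jon74E read 136.9 in old and 3146 in young flies, 23.0-fold lower, and the trypsin gene iotaTry and Jon44E were below the floor in old flies, at least 9.42-fold and at least 11.6-fold lower. Genes of sugar and starch digestion had a median of -1.20 (percentile 0), with 10 of 19 at least 2-fold lower, among them the amylase-related gene Amyrel (-3.36) and the maltase gene Mal-A7 (-3.43). Mal-B1 was the exception, 6.86-fold higher. The male accessory gland list, mainly genes of seminal fluid proteins, had a median of -0.89 (percentile 0). Of its 34 members 14 were at least 2-fold lower, such as Acp53C14c (-2.72), Mst57Dc (-1.79) and the sex peptide gene SP (-1.60). Odorant-binding protein genes had a median of -0.70 (percentile 0), with 12 of 29 at least 2-fold lower and Obp99b lowest at -3.36. Genes of oxidative phosphorylation (median -0.71, 18 of 76 at least 2-fold lower, 16 of them duplicate copies of a subunit), muscle contraction (-0.69, 9 of 23) and the TCA cycle (-0.65, 0 of 13) stood at percentiles 0, 0.02 and 0.945. Testis genes had a median of -0.40 (percentile 0.1) and cuticle genes of -0.40 (percentile 0.53).

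In all, 9714 genes were compared between the pools without curcumin, and 409 were at least 2-fold higher and 953 at least 2-fold lower in old flies, together 14.0% of those compared. The submitters' design text gives 1383 genes, or 7.3% of 18880 probe sets, with a significant age difference. That count came from a test not used here and is set beside the present counts only for orientation. Genes below the floor in young flies also included CG16995 (at least 8.02-fold higher), CG18557 (at least 6.33-fold) and Cyp304a1 (at least 4.77-fold), and genes below the floor in old flies included CG17192 (at least 11.6-fold lower) and CG18179 (at least 7.65-fold).

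**Figure D1:**
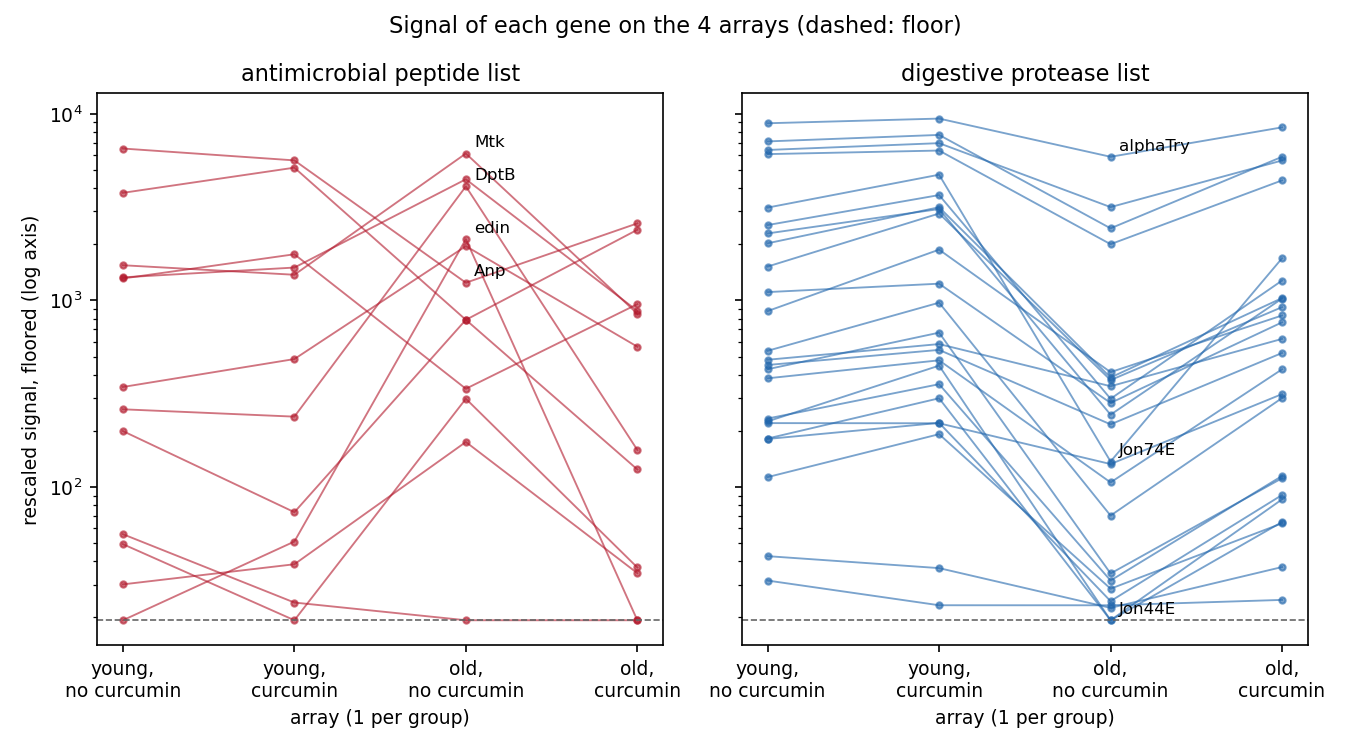
Rescaled and floored signal on a log axis of each measured antimicrobial peptide gene (left) and digestive protease gene (right) on the 4 arrays, with 1 line per gene and the floor of 19.3 dashed. On the old array without curcumin DptB reads 4087 and Jon74E 136.9, and on the old array with curcumin they read 158.0 and 1683.

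With curcumin, fewer genes differed at least 2-fold with age. Oxidative phosphorylation, muscle and digestive protease genes had negative list medians as without curcumin, while no antimicrobial peptide gene was at least 2-fold higher. Oxidative phosphorylation genes had a median of -0.86 and 20 of 76 were at least 2-fold lower. Muscle contraction genes had a median of -1.03, with 14 of 23 at least 2-fold lower, including the flight muscle troponin gene TpnC4 (37.5 in old and 1792 in young flies, 47.8-fold lower), Act79B (-2.65) and fln, which encodes flightin (-2.15). Genes of the TCA cycle had a median of -0.77, and of glycolysis of -0.47. Digestive proteases had a median of -1.23, with 13 of 24 at least 2-fold lower, and genes of sugar and starch digestion of -0.57, with 5 of 19. These list medians stood at percentile 0 to 1.14 of random lists. Antimicrobial peptide genes had a median of -0.64 (percentile 0.01), with 0 of 12 at least 2-fold higher and 3 lower. The 3 lower were edin, Anp and Drsl4, of which Anp and Drsl4 were also lower without curcumin. DptB read 158.0 in old and 238 in young flies. Immune recognition and signalling genes had a median of 0.15 (percentile 95.5), and PGRP-LB (1.14) and Listericin (1.25) were the 2 members at least 2-fold higher and TotC (-1.14) the 1 lower.

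UDP-glucuronosyltransferase genes had a median of 0.42 (percentile 100) for age on this diet, with Ugt37C2 (2.54), Ugt302K1 (1.37) and Ugt50B3 (1.25) as the 3 of 27 members at least 2-fold higher. Ugt37C2 was at 0.94 with the floor at the 60th percentile. Cytochrome P450 genes had a median of 0.21, with Cyp312a1 (2.15) and Cyp28c1 (1.79) highest among them. The accessory gland list, low in the other diet, had a median of -0.06 here, and its sign turned with quantile normalization (0.05) and without rescaling (0.06). Cuticle genes (-0.35, percentile 0.01), neuronal genes (-0.37, 0.03) and odorant-binding protein genes (-0.24, 0.34) were lower. The mitotic cell cycle list had a median of 0.39 (percentile 99.9), which was -0.13 with the floor at the 60th percentile of signals. Over 9751 genes, 293 were at least 2-fold higher and 256 at least 2-fold lower with age on curcumin food, 5.63% in all. Without rescaling, the median of all genes moved to 0.12 from -0.005, and the higher share of these genes was 69.7% in place of 53.4%. Centring on each array's median moved that share the other way, to 45.5%, and no floor to 46.6%. Bounds included Pvf2, a growth factor gene, at least 4.67-fold higher, and the cuticle gene Cpr92F, at least 11.1-fold lower, which in young flies was above the floor only with curcumin.

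Across both diets, Npc2e, MtnD and LysX had the largest mean differences upward with age, and TpnC4, CG12374 and CG13947 the largest downward. The rule took genes measured on all 4 arrays that differed at least 2-fold the same way in both diets, which held for 116 genes higher and 113 lower. The sterol-binding family gene Npc2e was 10.9-fold higher without and 28.6-fold higher with curcumin. The metallothionein genes MtnD (4.15-fold and 20.8-fold) and MtnB (3.21-fold and 14.3-fold) were higher by more on curcumin food, and the lysozyme gene LysX (11.3-fold and 5.42-fold) by less. Jhbp12, of a juvenile hormone-binding protein family, was 7.62-fold and 7.51-fold higher. The others among the 10 highest were the acetylcholine receptor subunit gene nAChRbeta3, Ugt37C2, CG2111, CG7381 and Mal-B1, with mean log2 differences from 2.75 for nAChRbeta3 to 2.41 for Mal-B1. The 10 lowest were led by TpnC4 at a mean of -4.69 and CG12374 at -4.47, followed by CG13947 (-3.67). Scp1, which encodes a sarcoplasmic calcium-binding protein, was 11.9-fold lower in both diets. The neuropeptide-like precursor gene Nplp3 (-3.53), CG7203 (-3.43), CG12057 (-3.40), the corneal lens gene retinin (-3.24), the protease gene Jon65Aii (-3.11) and CG18180 (-3.06) completed them. CG17192 was below the floor on both old arrays, at least 11.6-fold lower without and at least 27.6-fold lower with curcumin, and CG12947 was below it on both young arrays, at least 3.25-fold and at least 3.82-fold higher.

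In the additive limma model of age and curcumin over 9563 genes, 0 genes differed with age at a Benjamini-Hochberg adjusted p below 0.05, and the smallest adjusted p was 0.125. The unadjusted p was below 0.05 for 2236 genes, against 478 expected by chance, of which 1088 were higher and 1148 lower in old flies. limma with an intensity trend and a robust prior, and limma without the diet term, also called 0 genes, with 2312 and 2254 at an unadjusted p below 0.05. Centring on each array's median called 70 genes, and the floor at the 60th percentile called 8. The limma estimates for Npc2e (log2 4.14, SE 0.39), Jhbp12 (2.92, SE 0.17) and Scp1 (-3.57, SE 0.17) all had an adjusted p of 0.125. On the mean over diets, 274 genes were at least 2-fold higher and 409 lower in old flies. Without rescaling these counts were 343 and 338, so the excess of lower genes depended on scaling. Leaving out 1 array at a time gave 293 or 404 genes higher and 250 or 951 lower, the larger numbers where an array with curcumin was left out.

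**Figure D2:**
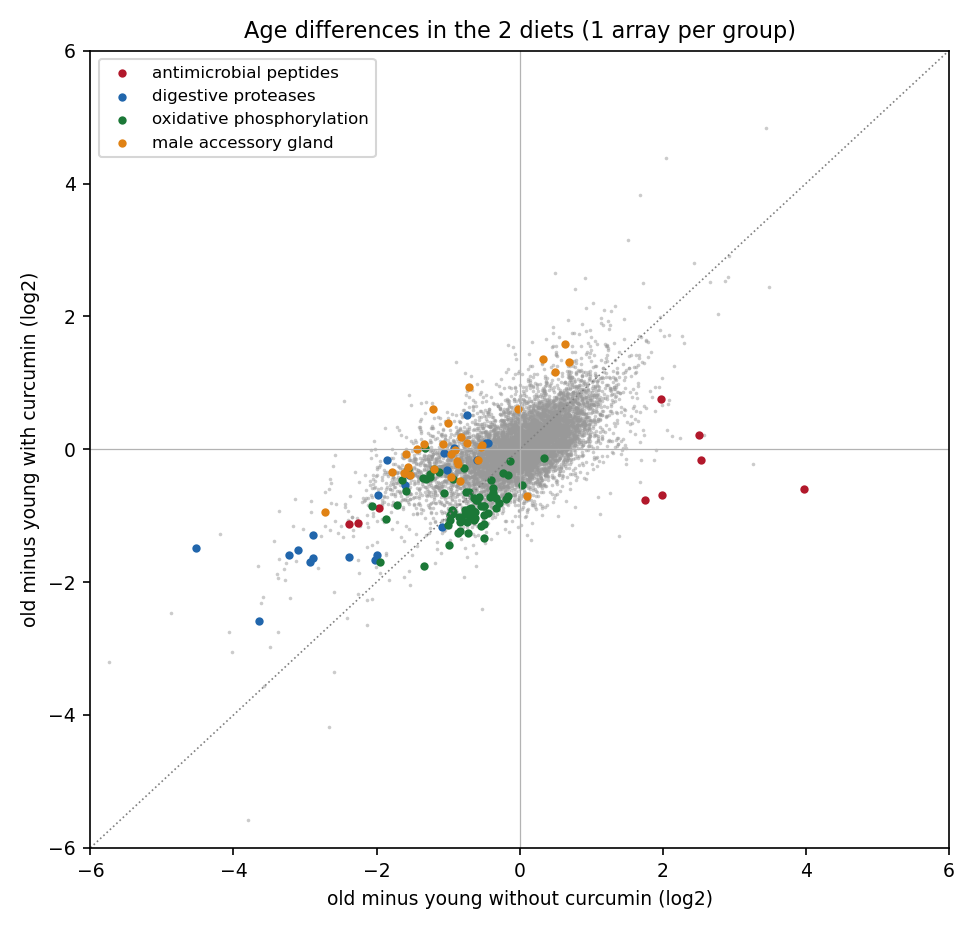
Log2 difference of old minus young flies without curcumin (x axis) against the same difference with curcumin (y axis) for the 8676 genes at or above the floor on all 4 arrays, with 4 gene lists in colour and the line of equal differences dotted. DptB lies at 3.97 and -0.59, and the digestive protease Jon74E at -4.52 and -1.49.

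The age differences of the diets ran in the same direction for most genes, with no array in common. Pearson's r across 9563 genes was 0.625 and Spearman's rho 0.611, across genes that are not independent replicates, and the slope of the differences with curcumin on those without was 0.458. Of the genes at least 2-fold lower with age, 951 without and 249 with curcumin among genes compared in both, 140 were shared, against 25.0 for independent lists. Of those at least 2-fold higher, 403 and 293, 128 were shared, against 12.5. The 951 genes at least 2-fold lower without curcumin had a median of -1.38 there and of -0.44 with curcumin, whereas the 249 genes chosen on curcumin food had -1.27 there and -1.16 without it. The corresponding medians of the 403 higher genes were 1.27 without and 0.77 with curcumin, and of the 293 genes 1.25 with and 0.92 without it. A list chosen by size in one pair has a smaller median in another pair by selection alone.

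In young flies, curcumin food went with higher signals for cuticle, muscle and energy metabolism genes. Cuticle genes had a median of 0.33 and 8 of 39 were at least 2-fold higher, and muscle contraction genes had a median of 0.51 and 4 of 23 at least 2-fold higher. Only 30 cuticle genes were at or above the floor on at least 2 of the 4 arrays. Some of the 39 therefore entered through 1 array, such as Cpr92F, and such a gene can only be higher on that array. Oxidative phosphorylation genes had a median of 0.48, digestive proteases of 0.38, the TCA cycle of 0.33, glycolysis of 0.30 and sugar and starch digestion of 0.25. All of these stood at percentile 99.9 or above, and single members were mostly under 2-fold. Quantile normalization gave smaller medians for the TCA cycle (0.20), glycolysis (0.17) and sugar and starch digestion (0.11). Among genes measured on both arrays the largest differences were CG13026 (8.18-fold higher), CG7203 (7.58-fold), Vajk2 (6.02-fold), the cuticle gene Cpr76Bd (4.14-fold), TpnC4 (3.73-fold) and Cpr100A (3.48-fold). Several of these were near the floor without curcumin, and with the floor at the 60th percentile Vajk2 was at 0.87 and Cpr76Bd at 0.72 log2. CG7214 and Cpr92F were below the floor in young flies without curcumin and read 345 and 214 with it, at least 17.9-fold and at least 11.1-fold higher, and Cpr97Ea (at least 5.92-fold) and Vajk3 (at least 4.92-fold) followed. The largest differences downward were Npc2e (3.76-fold lower), the stress peptide gene TotC (3.70-fold), CG3604 (2.81-fold), CG2983 (2.80-fold), Def (2.72-fold) and Ugt37C2 (2.69-fold), of which CG2983 was at -0.27 log2 with that floor. Osi6, of the Osiris family, read 132 without curcumin and was below the floor with it, at least 6.82-fold lower, and Dhc62B, CG13159 and ImpL1 were at least 3.53-fold, 3.47-fold and 3.15-fold lower.

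The antimicrobial peptides had a median of 0.02 in this comparison (percentile 71.3), with Def, AttD and Drsl3 at least 2-fold lower and edin higher as a bound of at least 2.64-fold. The median's sign turned with quantile normalization (-0.001) and without rescaling (-0.08). Lysozyme genes had a median of 0.42 over 3 members, or 0.10 with the floor at the 60th percentile. Phototransduction genes had a median of 0.11 (percentile 98.9), or 0.0071 without rescaling. Of 9767 genes compared, 38 were at least 2-fold higher and 40 lower with curcumin, 0.799% in all. A simulated pair of unchanged arrays with the noise of the limma prior had 347 of 9563 genes at least 2-fold apart. That noise holds any interaction, and no floor was applied to the simulated signals. The number is therefore no measure of chance for the young pair. Without rescaling, 33.0% of the genes past 2-fold were higher in place of 48.7%. Centring on each array's median gave 56.8% and the floor at the 60th percentile 65.2%, so the balance depended on processing both ways.

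In old flies, curcumin food went with lower antimicrobial peptide and higher digestive enzyme signals. The signs were opposite to those for age without curcumin, a comparison that shares the old array without curcumin and so tends to opposite signs with no change at all. Antimicrobial peptide genes had a median of -2.34 (percentile 0), with 8 of 11 at least 2-fold lower. DptB was 25.9-fold lower with curcumin, Mtk 7.22-fold, AttD 8.02-fold and Def 6.34-fold, and edin was below the floor, at least 110-fold lower. The 3 members at least 2-fold higher were Anp, Drsl4 and Drsl5. Immune recognition and signalling genes had a median of -0.54 (percentile 0), with PGRP-SB1 (-1.86) and Rel (-1.36) among 6 of 30 at least 2-fold lower. TotC was 13.6-fold lower and Diedel, a secreted immune-responsive protein, 14.9-fold lower, and NimC4, CG43085 and obst-H were below the floor with curcumin, at least 4.17-fold, 3.51-fold and 2.65-fold lower. Digestive proteases had a median of 1.36, with 19 of 24 at least 2-fold higher, and sugar and starch digestion of 1.24, with 11 of 19, both at percentile 100. Jon74E was 12.3-fold higher, CG12374 8.95-fold and CG5107 8.14-fold, followed by CG10910 (6.79-fold), CG31104 (5.98-fold) and CG43673 (5.84-fold).

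The accessory gland list had a median of 0.81 in old flies on curcumin food (percentile 100). Of its 34 members 13 were at least 2-fold higher, including Acp53C14c (1.74), Acp32CD (1.61) and Mst57Dc (1.59). Odorant-binding protein genes had a median of 0.43 (percentile 100), with Obp56a (2.15) highest among 8 of 29 at least 2-fold higher. Oxidative phosphorylation genes had a median of 0.30 (percentile 100), muscle contraction genes of 0.25 (98.8) and UDP-glucuronosyltransferase genes of 0.21 (99.3), with Ugt37A2 at 2.47. The genes iotaTry, CG14011, ND-51L1 and CG14708 were below the floor in old flies without curcumin and at least 4.45-fold, 3.87-fold, 3.86-fold and 3.86-fold higher with it. Of 9612 genes compared, 501 were at least 2-fold higher and 120 lower, so that 80.7% of these were higher with curcumin.

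Over both ages, 8 genes were at least 2-fold higher and 3 at least 2-fold lower with curcumin at each age among genes at or above the floor on all 4 arrays. AttD and Dhc62B, below the floor in young flies with curcumin, were also at least 2-fold lower at each age. The higher genes were CG7203 (7.58-fold in young and 2.65-fold in old flies), Nplp3 (2.14-fold and 4.20-fold), the flight muscle genes fln (2.37-fold and 3.23-fold) and TpnC41C (2.27-fold and 2.07-fold), Npc2d (2.18-fold and 3.30-fold), retinin (2.05-fold and 2.92-fold), the trypsin gene epsilonTry (2.13-fold and 2.01-fold) and the glutathione transferase gene GstD7 (2.88-fold and 2.29-fold). GstD7 was low, at 23.6 and 68.0 in young flies without and with curcumin and 23.6 and 54.1 in old flies. The lower genes were TotC (3.70-fold and 13.6-fold), Def (2.72-fold and 6.34-fold) and Ugt37C2 (2.69-fold and 3.37-fold). Ugt37C2 read 22.4 in young flies with curcumin, and with the floor at the 60th percentile it no longer differed in young flies and GstD7 no longer differed at either age, while CG7203 was at 0.34 log2 in old flies. Among genes below the floor on both arrays of a diet, Trissin was at least 1.87-fold and at least 2.31-fold lower with curcumin, and CG33017 was at least 1.35-fold and at least 1.90-fold higher.

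limma called 0 genes for the curcumin effect, with a smallest adjusted p of 0.829, and 344 genes, or 3.60%, had an unadjusted p below 0.05 against 478 expected by chance. The variants with an intensity trend and robust prior and without the age term also called 0, with 340 and 34 genes at an unadjusted p below 0.05. Ugt37C2 had a curcumin estimate of -1.59 (SE 0.19) and fln of 1.47 (SE 0.21) in limma, both with an adjusted p of 0.829. On the mean over ages, 72 genes were at least 2-fold higher and 20 lower. Leaving out 1 array gave 501 higher and 115 lower where a young array was left out, and 32 and 38 where an old array was left out. The curcumin differences at the 2 ages, which share no array, had r = 0.107 and rho = 0.10 across genes. With no floor r was 0.00561. Among 9390 genes compared at both ages, 8 were at least 2-fold higher at both, against 1.39 for independent lists, and 5 lower, against 0.42.

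**Figure D3:**
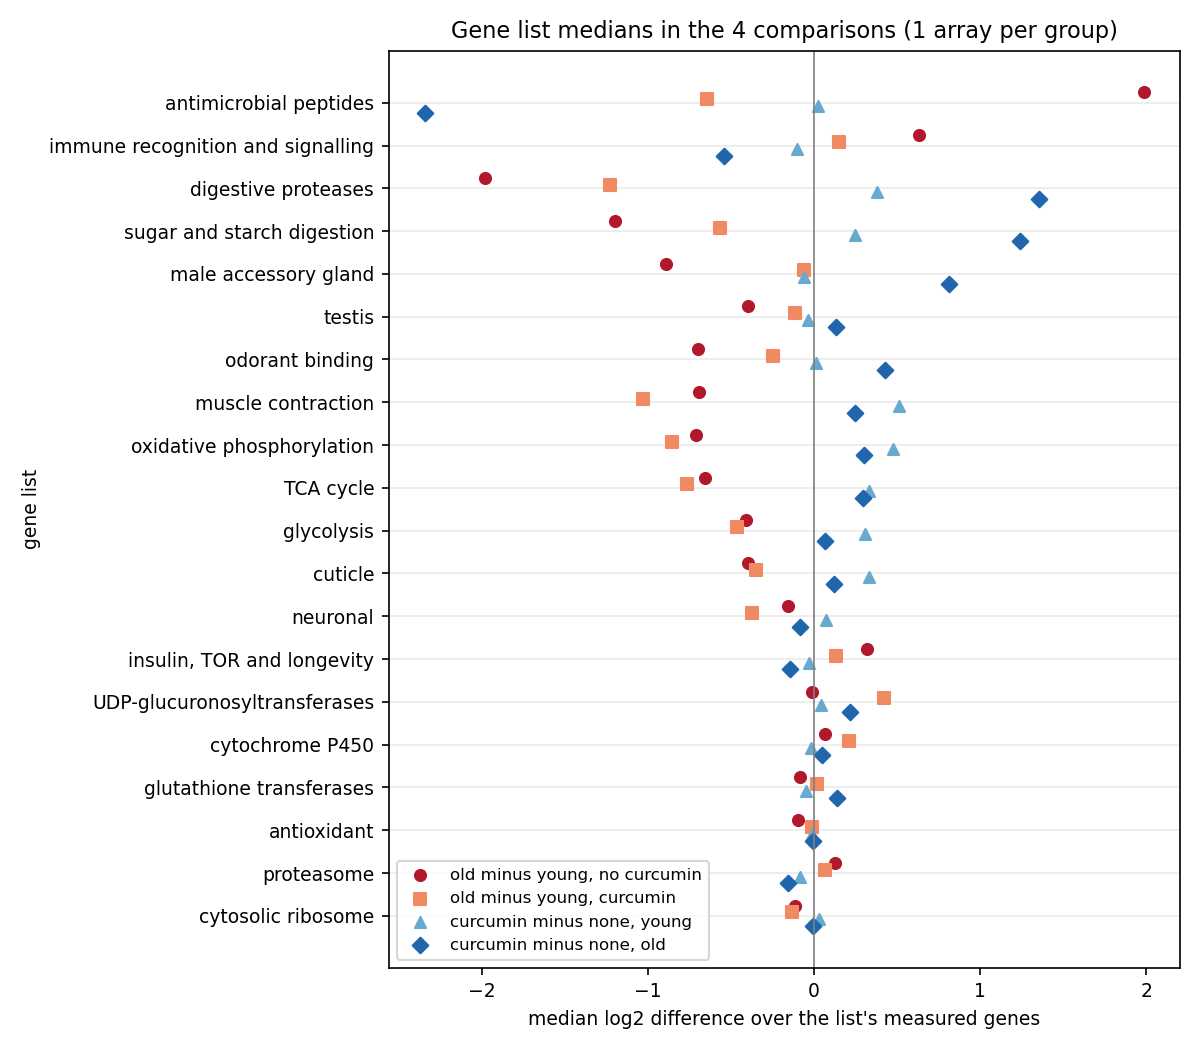
Median log2 difference over the measured genes of 20 gene lists in each of the 4 comparisons, with 1 mark per comparison and 1 array per group. The antimicrobial peptide list lies at 1.99 for age without curcumin and at -2.34 for curcumin in old flies, and the digestive protease list at -1.98 and 1.36.

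The difference of the curcumin differences, old minus young, was lowest for DptB and highest for CG10910 among genes at or above the floor on all 4 arrays. The 5 lowest values were DptB (-4.56), Diedel (-3.48), the cecropin gene CecB (-2.69), CG8534 (-2.69) and Mtk (-2.68), and the 5 highest were CG10910 (3.18), Jon74E (3.03), CG5107 (2.92), CG12374 (2.54) and CG3739 (2.50). It was at least 2-fold above 0 for 668 genes and at least 2-fold below for 188, and 4 arrays left no degrees of freedom to test it. These counts are of the undivided difference. Divided by 2, which puts it on the scale of the mean effects, it was at least 2-fold from 0 for 53 genes. On that scale curcumin had 92 such genes and age 683. Any difference in time on curcumin food between the ages enters the interaction too. The SD over genes, from the median absolute deviation, was 0.47 for age, 0.26 for curcumin and 0.23 for the interaction on the same scale, so the curcumin contrast was spread about as widely as the interaction that serves as its error. Differences between probe sets of the same gene were divided by the square root of 2 to give a spread per probe set. Over 422 pairs this SD was 0.28 for age and 0.17 for curcumin.

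The curcumin difference in old flies ran against the age difference without curcumin, with r = -0.805 across genes. These comparisons share the old array without curcumin, and unchanged simulated arrays gave r = -0.516. The covariance was -0.310 against -0.0999 simulated. For age over both diets and curcumin over both ages r was -0.650, against -0.029 simulated, but the old array without curcumin and the young array with curcumin enter these contrasts with opposite signs, so a deviation of either alone can give a negative r. Of the 951 genes at least 2-fold lower with age without curcumin, 436 were among the 501 at least 2-fold higher with curcumin in old flies, against 49.8 for independent lists. Simulated unchanged arrays shared 56 genes between lists of 170 and 164. Of the 404 genes at least 2-fold higher, 89 were among 115 lower with curcumin, against 4.86 for independent lists, and the simulated lists of 165 and 163 genes shared 60. The part of this excess due to the shared array cannot be split off. The simulated covariance and shared counts rest on noise that holds any interaction, with no floor applied, so their size is uncertain. The old array without curcumin lay at least 2-fold outside the range of the other 3 for 491 of 9563 genes, 410 below and 81 above, while the old array with curcumin did so for 11, the young array with curcumin for 41 and the young array without it for 7.

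Genes linked to lifespan were followed by name. The insulin receptor gene InR read 145 and 127 in young flies without and with curcumin and 515 and 233 in old flies, 3.55-fold and 1.85-fold higher with age. Its age estimate in limma was 1.36 (SE 0.29, adjusted p = 0.154). The kinase gene Akt was higher with age by 1.45 without and 0.86 with curcumin. The methuselah gene mth read 25.9 and 34.6 in young and 51.6 and 35.7 in old flies, close to the floor. The JNK gene bsk was within 1.10-fold in all 4 comparisons, from 427 to 485, and 1 other measured probe set of the gene went in the opposite direction with age in both diets and with curcumin in old flies. The list of insulin, TOR and longevity genes had a median of 0.32 for age without curcumin (percentile 99.2), with InR and Akt as its 2 members at least 2-fold higher, of 0.13 with curcumin, and of -0.03 and -0.14 for curcumin in young and old flies, the value in young flies turning sign with scaling. Thor was not named by the probe table used here.

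Several stress and housekeeping lists stayed near 0 or, with larger medians in small lists, within the central 95% of random lists. Antioxidant genes had medians of -0.09 and -0.01 for age without and with curcumin, and cytosolic ribosome genes of -0.11 and -0.13, and both lists turned sign under another scaling. Proteasome genes (0.13 and 0.06), glutathione transferases (-0.09 and 0.02), lipid metabolism (-0.11 and 0.11), circadian genes (0.15 and 0.12) and phototransduction genes (0.16 and -0.12) lay within the central 95% of random lists for both age pairs. So did heat shock genes (-0.31 and 0.0009), melanin and sclerotisation genes (-0.17 and -0.21), lysozymes (0.52 and -0.002) and the ovary and early embryo list (0.19 and 0.11). The heat shock and lysozyme lists held only 8 and 3 measured genes, so their random lists ranged widely. The heat shock, lysozyme and glutathione transferase values on curcumin food turned sign with scaling. Members still stood out. The lipase gene mag differed with age by -3.59 without curcumin, and GstE1 by 1.58. Of the larval serum list only Lsp2 was measured, at -2.50 and -1.16, and of the turandot list TotC alone was above the floor on all 4 arrays.

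Eggshell and yolk protein genes were near or below the floor on all 4 arrays, although each pool was labelled as both sexes. Of 19 eggshell genes, 17 were below the floor on every array, and the highest, Cp36, read 26.1. The yolk protein genes Yp1 and Yp2 were at most 27.4 and 20.9, and Yp3 lay between 43.6 and 57.9. Of 29 genes on the ovary and early embryo list, 14 were below the floor on every array, among them osk, bcd and vas. Another 14 were at or above it on every array. The brightest, mex1 at 1600, is named for midgut expression and is no marker of ovary or embryo. All 34 members of the accessory gland list were at or above the floor on at least 2 arrays. So were 34 of 35 testis genes, with a highest signal of 1300 for betaTub85D. The accessory gland list reached 9264, for the ejaculatory bulb gene Ebp, and it also holds the adult cuticle gene Acp65Aa. The dosage compensation RNAs of males were not named by the probe table used here.

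**Figure D4:**
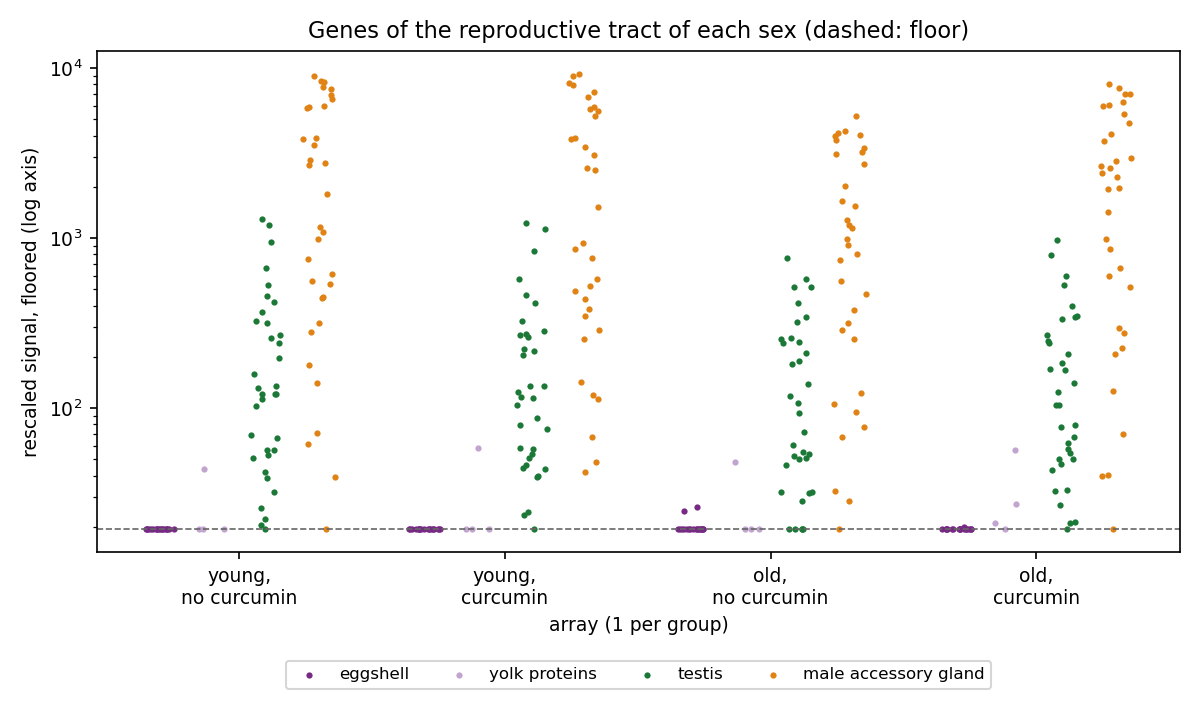
Rescaled and floored signal on a log axis of each gene of the eggshell, yolk protein, testis and male accessory gland lists on the 4 arrays, 1 point per gene, with the floor of 19.3 dashed. Eggshell genes reach 26.1 at most and the accessory gland list 9264, for the ejaculatory bulb gene Ebp.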

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

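All tests of explanations in this part were chosen after the results were seen. The median of the antimicrobial peptide list differed with age in opposite directions in the diets, at 1.99 without and -0.64 with curcumin. With 1 array per group this difference was not tested for significance. Not all members turned sign. Def (1.98 without and 0.76 with curcumin) and AttD (2.59 and 0.94) were higher with age in both diets, and Anp and Drsl4 were at least 2-fold lower in both. DptB (3.97 and -0.59), CecB (2.54 and -0.16) and Mtk (1.99 and -0.69) turned sign but were less than 2-fold lower with curcumin. Among genes measured on all 4 arrays, 1 differed at least 2-fold with age in opposite directions, CG8534, at 1.39 without and -1.30 with curcumin, again not tested for significance, and 0 genes did so for curcumin between the ages. Among the probe sets with no gene name here, 1012 of 4721 could be compared between the arrays without curcumin, and 49 were at least 2-fold higher and 34 at least 2-fold lower in old flies.

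The old array without curcumin combined high immune and low digestive gene signals, and its neighbours in age and diet did not. A factor per array moves both lists alike and cannot change the gap of 3.97 log2 units between their medians for age without curcumin. This argues against such a factor as the cause of the gap. Under quantile normalization, the only scaling used that could change it, the gap stayed above the summed spread of the members, 3.55. That scaling keeps the order of genes within an array, and the lists were picked for this pattern, so other scaling biases stay open. The median interaction was 1.06 for the digestive proteases, with a spread of 0.54, and -1.97 for the antimicrobial peptides, with a spread of 2.48, but these values restate the readings of that array and leave open whether curcumin acts alike at both ages. A state of that single pool, such as infection or feeding, may also give the 491 genes for which this array lay outside the other 3, and so may curcumin in old flies. With 1 pool per group these cannot be told apart.

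Eggshell and yolk protein genes were near or below the floor on all 4 arrays. On all arrays, 18 of 23 eggshell and yolk protein genes were below the floor, and the highest of 10000 random lists had 12. This count restates the pattern, and random lists are not matched on how widely genes are expressed. Failing probe sets therefore stay open. Few or no females in the pools stay open, since the highest signal of any of these genes, 57.9, restates the pattern and does not set this explanation above others. Females present but not making eggs also stay open, since Yp1 read 27.4 at most and these data do not show whether the fat body would keep making yolk protein in such females.

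Muscle and respiratory chain genes were higher on the young array with curcumin than on the young array without it. Under quantile normalization both medians, 0.47 and 0.39, stood at percentile 100 of lists matched on expression, so most genes of like brightness differed less. The lists were picked for this pattern and stood at percentile 100 before that scaling too. The result therefore restates the pattern and does not settle whether a bias that follows signal brightness plays a part. The medians of the TCA cycle and glycolysis fell to 0.20 and 0.17, and such a bias stays open. Younger flies in that pool may account for the higher signals, with the young flies labelled 1 to 3 days, both titles giving day 1 and the design text 3 days. The difference between the young arrays ran against the age contrast over genes, with r = -0.318. Curcumin acting against age gives the same sign. So does any deviation of the young array with curcumin alone, which enters the difference and the age contrast with opposite signs. This r therefore favours none of these, and they cannot be told apart with 1 pool per group.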

How the results depend on the processing

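No paired analysis was possible because no label links individual pools, and the additive model compared arrays only within diet and within age. Every list median outside the central 95% of random lists kept its sign under all 8 alternatives that rework the matrix except the mitotic cell cycle list for age with curcumin, which was -0.13 with the floor at the 60th percentile. That floor also moved the cuticle list for age with curcumin to -0.72 and the lysozyme list for curcumin in young flies to 0.10. Of 736 values of named genes under alternatives, 676 moved by less than the spread per probe set, taken from pairs of probe sets of a gene, and 60 by more. No difference of at least 2-fold turned sign. The curcumin effect kept 0 calls under every alternative that gave a test, with a smallest adjusted p from 0.743 to 1.000. For age, centring on each array's median called 70 genes with a smallest adjusted p of 0.0246, and the floor at the 60th percentile called 8, with 0.0485. Over all settings that p ranged from 0.0246 to 0.369. The model without the age term left 34 genes at an unadjusted p below 0.05 for curcumin. Without rescaling, 61 genes were lower with curcumin in young flies.

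The counts moved with the floor and the threshold, and the cause was not tested. Interaction counts are of the undivided difference, so they are not on the scale of the mean effects. With no floor, higher and lower counts were 847 and 1736 for age without curcumin, 790 and 905 for age with it, 525 and 559 for curcumin in young flies, 1175 and 599 in old flies, 596 and 1047 for the mean age effect, 492 and 360 for the mean curcumin effect, and 1563 and 853 for the interaction. The correlations were then 0.303 between the age differences, 0.00561 between the curcumin differences, -0.667 between age without curcumin and curcumin in old flies, and -0.347 between the mean effects. With the floor at the 25th percentile, 457 genes were lower with age on curcumin food, 164 and 179 were higher and lower with curcumin in young flies, 234 were lower in old flies, 140 and 50 were higher and lower for the mean curcumin effect, and the interaction had 1023 and 390. With the floor at the 60th percentile, 455 genes were lower with age without curcumin, 190 higher and 155 lower with age on it, 15 and 8 with curcumin in young flies, 263 and 69 in old flies, 224 lower for the mean age effect, 46 and 8 for the mean curcumin effect, and 293 and 78 for the interaction. With the pseudocount, 191 were higher with age on curcumin food, 20 lower with curcumin in young flies, 301 higher in old flies, 177 and 245 for the mean age effect, 46 higher for the mean curcumin effect, and 370 and 97 for the interaction. At 3-fold, the counts were 94 and 318, 63 and 77, 10 and 7, and 101 and 30 for the 4 pairs in the same order. Leaving out each array gave 250 to 951 genes lower with age, 32 to 501 higher and 38 to 115 lower with curcumin, as values with no test. Signal over background limited which genes could be compared, with 16.6% below the floor on all 4 arrays, and of the 953 genes lower with age without curcumin 799 were at or above it on both arrays.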

Other observations

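The metallothionein genes, which encode metal-binding proteins, were followed as a family after MtnB and MtnD had been seen among the genes highest with age. MtnB read 50.8 and 38.5 in young flies without and with curcumin and 163 and 549 in old flies, and MtnD read 92.3, 52.6, 383 and 1097. MtnC differed with age by -0.88 without curcumin and by 1.32 with it. MtnA, the brightest, differed by 0.15 and 0.33. In old flies MtnB, MtnC and MtnD were higher with curcumin by 1.75, 1.51 and 1.52, and in young flies the differences were -0.40, -0.69 and -0.81.

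The oxidative phosphorylation list held genes of different behaviour, separated after their values were seen. Its 18 measured members named as duplicate copies of a subunit, several of which are known for expression in the testis, had a median of -1.33 for age without curcumin and -0.44 with it, and 16 were at least 2-fold lower without it. The 58 other members had medians of -0.63 and -0.94. For curcumin the duplicates had -0.06 in young and 0.82 in old flies, and the others 0.55 and 0.19. The signs held under all 4 scalings, with the duplicates from -0.16 to -0.01 in young flies. Dopa decarboxylase, Ddc, read 862 in old flies without curcumin and between 226 and 251 on the other 3 arrays.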
